A study of Mus musculus with 6 samples.

How the data were processed

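The series measured gene expression by RNA sequencing in cells of the embryonic mouse cortex that had taken up plasmid DNA by in utero electroporation. Per the labels' protocols, a plasmid expressing green fluorescent protein (GFP) at 0.7 µg/µl was mixed with a plasmid at 1 µg/µl that drives a short hairpin from the U6 promoter. The hairpin was either a precursor of the microRNA miR-3607 (the Mir group) or the scrambled control supplied with the vector (the Scr group). A volume of 1 µl was injected into the lateral ventricle at E14.5 (embryonic day) and driven into the cells by 5 pulses of 45 V, each 50 ms long and 950 ms apart. GFP-positive cells were collected by flow sorting 24 hours later, at E15.5. Each library came from the pooled cells of 2 embryos, with 3 independent pools per group, so that p-values measure the spread between pools of animals. The labels name the strain in conflicting ways, as ICR in the protocol and as C57BL/6 in the sample characteristics. RNA with an integrity number above 9.5 was made into libraries with the SMART-seq v4 kit, which amplifies full-length cDNA and does not mark the strand, and was read as 50 bp single reads.

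The values analysed were whole-number read counts per gene for each library, deposited by the authors without normalization. Per the submitters' processing notes, the tools named are HISAT2 2.1.0, HTSeq 0.11.0 and DESeq2 1.18.1, and the genome build is mm10 (GRCm38). The strand setting, the annotation and the handling of reads with several matches are not given in the sources used here. Each deposited count table held 54146 genes, of which 54079 had a symbol in the annotation, and 5 summary lines that name no gene. These summary lines were kept out of library sizes and tests. They listed 28.8 to 31.6% of reads as falling in no feature, 0.357 to 0.376% as ambiguous, 4.48 to 5.48% as not aligned and 39.3 to 44.4% as not uniquely aligned. From 21.9 to 23.6% of the listed reads of a library were assigned to genes. Of the noncoding genes lying at least 90% inside the exons of a well-covered gene on the opposite strand, 54 could be compared with that gene. Their median ratio of counts per kb was 1.30, and 70.4% had a ratio of at least 0.5, so that antisense and overlapping genes are reported as uncertain, as are genes with near-identical copies. Amplified reads without molecular identifiers are not independent molecules, and intervals from counts cover counting error only.

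Libraries of a group were compared before averaging. The chi-square per degree of freedom between libraries of a group was 8.23 to 28.2, so no library repeated another. Pearson correlations of log2 CPM (counts scaled to a common library size) across genes were 0.960 to 0.978 within groups and 0.934 to 0.976 between groups.

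Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test (two-sided) with group as the sole term and normalization by the trimmed mean of M values, whose factors were 0.992 to 1.01. The filterByExpr filter left 16897 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. The common dispersion corresponded to a biological coefficient of variation of 23.6%, with 3.60 prior degrees of freedom. Fold changes are Mir over Scr on the log2 scale, given ± their standard error from the F statistic, and levels are mean CPM ± SD over 3 libraries per group. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as alternatives, and 3612 genes without an adjusted p from DESeq2 stayed uncalled there.

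A total of 29 gene lists (pathways, cell states and markers of other cell types that the gate could hold) were fixed from textbook knowledge. Those with at least 3 tested members, 28 lists, were tested with camera, a competitive test of a list against all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the 28 lists. The same lists were tested with a correlation estimated for each list and with fry, which asks whether the genes of a list move on balance to a single side. Fry also gives a mixed p, which asks whether the genes of a list change at all, up or down. Medians per library were taken on log2 (CPM + 0.5), relative to the mean of the Scr libraries. Library composition was compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

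For microRNA sites, the mature strand was read from the hairpin oligonucleotide in the labels as the segment after the loop, GCATGTGATGAAGCAAATCAGT. Its seed, bases 2 to 8, is CATGTGA. Matches TCACATG and CACATGA, with the 8mer TCACATGA, were searched in the 3′ UTR of the transcript with the longest coding sequence of each gene, from GENCODE M21 on GRCm38. UTRs and coding sequences shorter than 8 nt were not searched. The planned measures were the difference of median fold changes between genes with and without a site, its rank among 7-mers held by at least 20 genes, and camera. After this result had been seen, each 7-mer was also scored by the mean rank of the fold changes of the genes that hold it, once trends with sequence length, mean expression and GC content were removed. This score is a z, the difference from the mean of all genes in standard errors, and it treats genes as independent although they are not.

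The groups, tests, gene lists, seed and alternatives were fixed before the data were examined. So was the rule for naming genes. It takes up to 10 genes per direction with the largest fold changes among those past the edgeR threshold that had a mean of at least 5 CPM, a symbol that is not a gene-model name and no overlap between the 6 libraries of both groups. Where fewer qualified, up to 5 further genes per direction with the smallest p under the same conditions were added and are named as not passing. It always takes Apc, Ctnnb1, Axin2, Lef1, Ccnd1, Pax6, Sox2, Hes1, Hes5, Eomes, Tbr1, Neurod2 and Cdh2, and in each list up to 4 members with the smallest p. Ftl1 and the sites of Fzd8 were looked at outside this rule, after values had been seen.

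Alternatives covered other scalings (DESeq2-type size factors, upper quartile, library totals), DESeq2, limma-voom, a robust edgeR fit, no filter and a filter of 50 counts on average. They also covered a threshold of 0.1, a fold limit of 1.5, leaving out 138 mitochondrial, haemoglobin and ribosomal protein genes, the replicate number as a block, and each library left out in turn. After the data had been seen, fits without Scr replicate 2 and Mir replicate 3, and with the summed endothelial markers of each library as a covariate, were added. Tables and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.

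The tests were tried on counts simulated for 16897 genes from the means and depths of these libraries. For this comparison edgeR called 3 of 67 genes changed by 1.5-fold, 24 of 67 changed by 2-fold and 50 of 66 changed by 4-fold, and 6 of 16664 unchanged genes. DESeq2 called 18, 40 and 58 genes of the same sets and 43 of the 16664 unchanged genes, out of 165 calls. Camera called the G2/M list planted at 1.3-fold and 0 of the 27 other lists. Genes were drawn independently here, so this does not show how often camera calls lists whose genes move together. The 7-mer score ranked each of 10 planted 7-mers at 1, and its lowest z with shuffled fold changes was -3.43. Shuffling breaks the links between genes and those with sequence length, expression and GC content. The value of -3.43 is therefore not a chance limit for the real fold changes.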

Results

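The data were 6 libraries from sorted cells of the mouse cortex at E15.5 (embryonic day), 3 with the miR-3607 hairpin (Mir) and 3 with a scrambled hairpin (Scr). Electroporation at E14.5 reaches cells that line the ventricle, most of them cortical progenitors, and the sort kept cells that carried GFP 24 hours later. The comparison asks what an excess of miR-3607 does to gene expression in these cells and, as the title of the series puts it, to the Wnt/β-catenin pathway. Counts in genes were 12724511, 13960806 and 16684038 in Scr replicates 1, 2 and 3, and 15847663, 15674262 and 14671557 in Mir replicates 1, 2 and 3.

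Genes of cell division and of cortical progenitors ranked higher in Mir than in Scr as lists, and markers of cortical neurons ranked lower, in camera with a preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.511 for radial glia and 0.424 for the others), and 0 lists were called with the directional form of fry. All 34 G2/M genes had a higher mean in Mir, with a median log2 fold change of 0.37, and 14 of 15 intermediate progenitor markers did, with a median of 0.39. Markers of inhibitory neurons, endothelial cells and microglia had lower means throughout, with medians of -1.60, -2.65 and -1.46 (adjusted p = 0.424 with an estimated correlation for each). These came mainly through low Mir replicates 1 and 2, and Scr replicate 2 was the highest library for inhibitory neurons and endothelial cells. With all 6 libraries and no covariate, the 3 Wnt/β-catenin lists were called in neither direction. Among single genes, the ferritin pseudogene Ftl2-ps was lower in Mir and no other gene passed the edgeR threshold. For this gene, a variant that differs between pools of embryos cannot be told apart from an effect of the hairpin.

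Of 16897 genes tested, edgeR called 0 higher and 1 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1110 genes higher and 1340 lower, 2450 in all, where 845 would arise by chance if genes were independent. Grouping Scr replicate 1 with Mir replicates 1 and 2 against the other libraries gave 2229 such genes, and the remaining false groupings gave 267 to 782. The excess can therefore not be assigned to the hairpin alone. The second smallest adjusted p of edgeR was 0.155. DESeq2 called 247 genes higher and 333 lower, and limma-voom 0 and 0. Over all genes tested, 3380 (20%) had no overlap between the 3 Mir and the 3 Scr libraries, which chance gives for 10% of genes. In the simulated data 43 of 165 DESeq2 calls were unchanged genes. DESeq2 calls moved with single libraries, to 46 higher and 72 lower without Mir replicate 2, 110 and 115 without Mir replicate 1, 148 and 159 without Scr replicate 3, 311 and 194 without Scr replicate 2, and 318 and 821 without Mir replicate 3. With Scr replicate 2 and Mir replicate 3 both left out, a choice made after seeing the data, edgeR called 10 genes higher and 19 lower.

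Ftl2-ps (ENSMUSG00000082062) is an annotated processed pseudogene of the ferritin light chain on the plus strand of chromosome 4, from 125504288 to 125504839. It was at 11.3 ± 3.77 CPM (SD, n = 3) in Scr and 0.0651 ± 0.00238 CPM (SD, n = 3) in Mir, a log2 fold change of -7.27 ± 0.43 with an adjusted p of 0.00487 by edgeR and 4.66e-12 by DESeq2. The counts behind these levels were 201, 125 and 153 in the Scr libraries and 1 in each Mir library. The ratio of the groups, Scr over Mir, was 170 with an exact 95% counting interval of 57.8 to 828. Ftl1, the functional ferritin light chain gene, had a log2 fold change of -0.15 ± 0.19 with an edgeR adjusted p of 0.751. Of the 25-base words in the 552 nt of the pseudogene, 73.9% also occur in Ftl1, so its counts are uncertain where reads could match both. The edgeR adjusted p was 0.0946 without Mir replicate 1 and 0.102 without Mir replicate 2, with a log2 fold change of -7.25 in each case, and limma-voom and the edgeR fit with the endothelial covariate called 0 genes.

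The genes with the smallest p among those that did not pass the edgeR threshold are given next; by the naming rule, their 3 Mir libraries lay all above or all below the 3 Scr libraries. Higher in Mir were Prag1 (a pseudokinase scaffold; 1.20 ± 0.13), Sfrp1 (a secreted Wnt antagonist; 0.70 ± 0.09), Racgap1 (needed for cytokinesis; 0.69 ± 0.08), Magt1 (a magnesium transporter; 0.82 ± 0.12) and Ccn1 (a matricellular protein and YAP target; 1.19 ± 0.17). Lower in Mir were Fbxo25 (an F-box protein; -0.85 ± 0.10), Ank3 (ankyrin-G of the axon initial segment; -0.77 ± 0.10), Fzd3 (a Frizzled receptor used in axon guidance; -0.63 ± 0.08), Edil3 (an integrin-binding matrix protein; -0.77 ± 0.10) and Ntrk3 (the receptor of neurotrophin-3; -0.66 ± 0.09). Their edgeR adjusted p-values were 0.155 for Prag1 and Fbxo25 and 0.159 for the other 8 genes. DESeq2 called each of the 10, with adjusted p-values from 2.11e-10 for Prag1 to 2.38e-06 for Magt1 and Edil3, and edgeR called each when no filter on low counts was used, with adjusted p-values from 0.00815 to 0.0453.

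In the Wnt/β-catenin pathway, the transcript of β-catenin itself was slightly higher in Mir and that of Apc, the scaffold of the complex that marks β-catenin for degradation, was lower, but neither passed the edgeR test. Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507) was at 989 ± 6.02 CPM in Scr and 1203 ± 30.6 CPM in Mir (SD, n = 3), a log2 fold change of 0.28 ± 0.06 with an edgeR adjusted p of 0.198. Apc (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552) was at 168 ± 24.3 CPM in Scr and 118 ± 2.03 CPM in Mir (SD, n = 3), a log2 fold change of -0.51 ± 0.11 with an edgeR adjusted p of 0.206. For both genes the 3 Mir libraries lay outside the range of the 3 Scr libraries, and DESeq2 called both, with adjusted p-values of 0.00528 and 0.00737. The pathway's feedback target Axin2 was at -0.19 ± 0.27 (edgeR adjusted p 0.784), and it was at 0.03 without Scr replicate 2. The transcription factor gene Lef1 was at -1.48 ± 0.64 (edgeR adjusted p 0.350), with 5.16 CPM in Mir replicate 3 against a Scr mean of 6.73 ± 2.1 CPM (SD, n = 3). The cyclin gene Ccnd1 was at -0.04 ± 0.21 (edgeR adjusted p 0.952), and at -0.28 without Mir replicate 3.

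Of 20 measured Wnt target genes, 7 had higher and 13 lower means in Mir, with a median of -0.23 and a camera adjusted p of 0.266. The list came past the threshold without Mir replicate 3, at a camera adjusted p of 0.0137, and turned upward with the endothelial covariate, at 0.173. Its members with the smallest p were Id2 (an inhibitor of basic helix-loop-helix factors; -0.52 ± 0.10), Ephb3 (an ephrin receptor; 0.80 ± 0.22), Znrf3 (a ligase that removes Frizzled receptors; 0.50 ± 0.20) and Tcf7 (a partner of β-catenin; -0.89 ± 0.38). Of 31 Wnt inhibitors and members of the destruction complex, 14 had higher and 17 lower means, with a median of -0.07 and a mean of -0.02, while camera pointed up at an adjusted p of 0.361 (0.0492 without Scr replicate 2). Sfrp1, Axin1 (a scaffold of the destruction complex; 0.61 ± 0.12) and Gsk3a (a kinase of that complex; 0.31 ± 0.09) were among its 4 members of smallest p, beside Apc. Of 30 Wnt activators, 16 had higher and 14 lower means, with a median of 0.07 and a mean of -0.14, and camera pointed up at an adjusted p of 0.731, but down without Scr replicate 3 (0.647) or Mir replicate 3 (0.581). Fzd8, a Frizzled receptor, was at 0.96 ± 0.14 and Rspo3, a secreted enhancer of Wnt signals, at -1.66 ± 0.37. Over all genes 0 members of these lists passed edgeR, and adjusted over the list alone 0 higher and 1 lower of the targets passed, 2 and 1 of the inhibitors and 3 and 2 of the activators. DESeq2 gave the same counts for each of the 3 lists. With the endothelial covariate the camera adjusted p of the inhibitors was 0.0263 and that of the activators 0.0116, both upward.

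**Figure D1:**
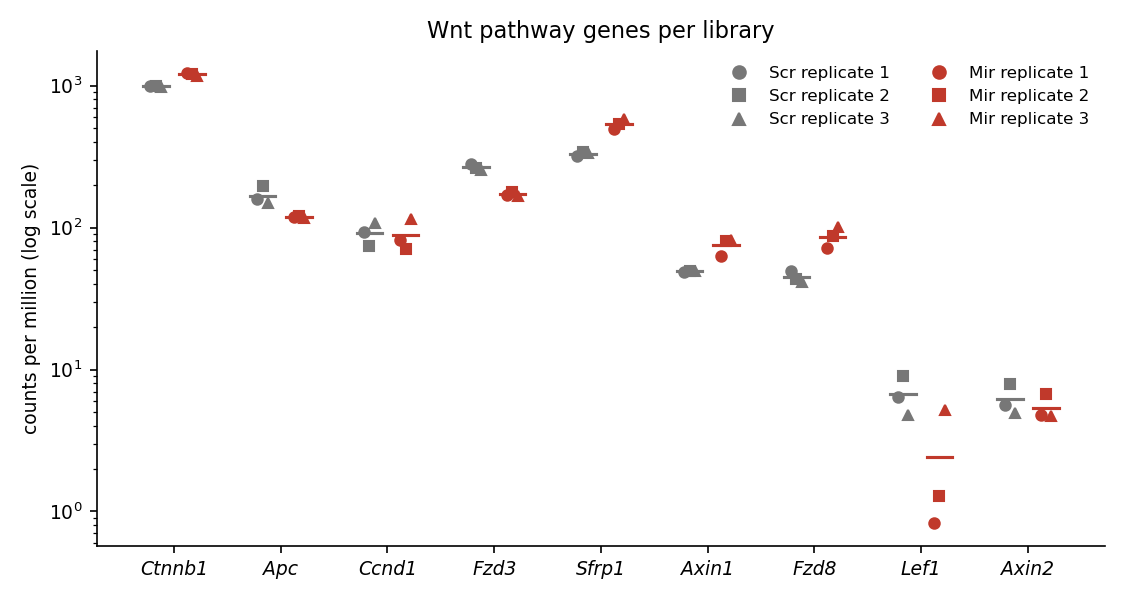
Levels in CPM (log axis) of 9 genes of the Wnt pathway in each library, with Scr in grey, Mir in red, and a bar at each group mean. Ctnnb1 was at 989 CPM in Scr and 1203 CPM in Mir, Apc at 168 and 118 CPM, and Lef1 in Mir replicate 3 at 5.16 CPM.

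Progenitor genes ranked higher and neuronal genes lower in Mir, by amounts that differed between libraries. Of 31 radial glia (apical progenitor) markers, 27 had higher means, with a median of 0.22 and a camera adjusted p of 5.93e-05 (adjusted p = 0.511 with an estimated correlation). Among them were Lhx2 (a LIM homeobox factor; 0.68 ± 0.17), Tnc (tenascin-C; 0.90 ± 0.26), Mfge8 (0.55 ± 0.16) and Sox21 (0.54 ± 0.18). Of the radial glia factors named in advance, Pax6 was at 0.41 ± 0.22, Sox2 at 0.11 ± 0.16, and the Notch effectors Hes1 at 0.14 ± 0.34 and Hes5 at 0.17 ± 0.17, with edgeR adjusted p-values of 0.445, 0.786, 0.891 and 0.681. Hes1 was at -0.26 and Sox2 at -0.09 without Mir replicate 3. The radial glia call ended without Mir replicate 3, at a camera adjusted p of 0.286, and turned downward without Scr replicate 2 and Mir replicate 3, at 0.721. Median levels of the list against the Scr mean were 0.03, 0.15 and 0.51 in Mir replicates 1, 2 and 3 and 0.07, -0.28 and 0.11 in Scr replicates 1, 2 and 3, so that Mir replicate 1 lay below Scr replicates 1 and 3.

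Of 15 intermediate progenitor markers, 14 had higher means in Mir, with a camera adjusted p of 3.08e-06 (adjusted p = 0.424 with an estimated correlation). Dll1, a Notch ligand, was at 0.49 ± 0.09, the antiproliferative gene Btg2 at 0.75 ± 0.18, and the transcription factor genes Insm1 at 0.55 ± 0.15 and Neurog2 at 0.57 ± 0.21. Eomes, the defining factor of these cells, was at 0.65 ± 0.31 with an edgeR adjusted p of 0.388. The median level of the list was 0.53, 0.57 and 0.07 in Mir replicates 1, 2 and 3 and 0.29, -0.36 and 0.01 in Scr replicates 1, 2 and 3, so that Mir replicate 3 lay below Scr replicate 1. The camera adjusted p was 0.133 with the endothelial covariate. Of 31 cortical neuron markers, 10 had higher and 21 lower means, with a median of -0.32 and a camera adjusted p of 5.93e-05 (adjusted p = 0.424 with an estimated correlation). The median level of this list was -0.19, -0.37 and -0.23 in Mir replicates 1, 2 and 3 and -0.13, 0.25 and -0.01 in Scr replicates 1, 2 and 3. Scr replicate 2 was also the highest library for inhibitory neuron markers (median 1.23), and whether inhibitory neurons add to the neuronal levels was not tested. The RNA-binding protein gene Elavl3 was at -0.56 ± 0.08, the synaptic gene Snap25 at -0.90 ± 0.18, the splicing factor gene Rbfox1 at -0.79 ± 0.24 and Sox5, a factor of deep-layer neurons, at -0.35 ± 0.11. Tbr1 and Neurod2, factors of early and of all excitatory cortical neurons, were at 0.04 ± 0.13 and 0.08 ± 0.08, with edgeR adjusted p-values of 0.919 and 0.689; Tbr1 was at -0.05 without Scr replicate 3. Adjusted over the list alone, edgeR called 0 radial glia, 3 intermediate progenitor (all higher) and 2 neuronal markers (both lower), and DESeq2 called 3, 3 and 4.

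Both cell cycle lists ranked higher in Mir in the camera test. All 34 G2/M genes had higher means, with a camera adjusted p of 8.28e-15, and so did 32 of 35 G1/S genes, with a median of 0.27 and a camera adjusted p of 9.63e-10 (adjusted p = 0.424 with an estimated correlation, for each of the 2 lists). The mitotic genes Gtse1, Tpx2, Kif20a and Ect2 were at 0.77 ± 0.14, 0.65 ± 0.18, 0.47 ± 0.14 and 0.41 ± 0.13. The S phase regulator E2f1 was at 0.72 ± 0.10, and the replication genes Rrm1, Mcm2 and Fen1 were at 0.57 ± 0.11, 0.44 ± 0.12 and 0.47 ± 0.14. The median level of the G2/M list was 0.36, 0.31 and 0.56 in Mir replicates 1, 2 and 3, and 0.10, -0.39 and 0.29 in Scr replicates 1, 2 and 3, so that Scr replicate 2 stood apart. Of 12 cell cycle inhibitors 9 had higher means, with a median of 0.19 and a camera adjusted p of 0.0324 (adjusted p = 0.424 with an estimated correlation). Cdkn2c was at 0.71 ± 0.17, Cdkn1c, which marks cells leaving the cycle, at -0.65 ± 0.16 and Tob1 at 0.30 ± 0.13, beside Btg2. This call was lost without Scr replicate 3 (camera adjusted p 0.0769), without Mir replicate 2 (0.133), with the filter at 50 counts (0.0662) and with the endothelial covariate (0.0518). In each list, edgeR adjusted over the list alone called 1 G2/M gene and 2 G1/S genes higher, and 2 inhibitors higher and 1 lower, none of them over all genes; DESeq2 called 2 and 4 higher, and 2 higher and 1 lower.

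Among signalling lists, Sonic hedgehog genes and Hippo/YAP targets ranked higher in Mir. Of 12 Sonic hedgehog genes 11 had higher means, with a median of 0.38 and a camera adjusted p of 0.00129 (adjusted p = 0.424 with an estimated correlation). They included the signal transducer Smo (0.55 ± 0.10), the co-receptors Boc (0.40 ± 0.14) and Gas1 (0.48 ± 0.25), and Sufu, a repressor of the pathway (0.42 ± 0.20). Of 15 Hippo/YAP genes 11 had higher means, with a median of 0.26 and a camera adjusted p of 0.000614 (adjusted p = 0.424 with an estimated correlation), among them Ccn1, Amotl2 (0.66 ± 0.13), Ccn2 (1.00 ± 0.35) and Ajuba (0.71 ± 0.30). Both calls were lost without Scr replicate 2 and Mir replicate 3, at camera adjusted p-values of 0.0643 and 0.0850. Immediate early and heat shock genes also ranked higher, with 10 of 13 means higher, a median of 0.18 and a camera adjusted p of 0.000715 (adjusted p = 0.424 with an estimated correlation). Here the libraries of the Mir group parted: Egr1 was at 307, 345 and 58.5 CPM and Fos at 75.4, 113 and 13.4 CPM in Mir replicates 1, 2 and 3, against Scr means of 41.2 ± 18.7 and 15.3 ± 3.81 CPM (SD, n = 3). Jun was at 0.63 ± 0.12 and Fosb at 2.70 ± 0.73. With p-values adjusted over the list alone, edgeR called 1 Sonic hedgehog, 2 Hippo/YAP and 4 immediate early genes, all higher, and DESeq2 called 1, 2 and 3.

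The 10 measured protein genes of the mitochondrial genome had a median of -0.31, 9 of them with lower means, and a camera adjusted p of 0.000155 (adjusted p = 0.424 with an estimated correlation). The subunit genes mt-Nd4, mt-Cytb, mt-Nd6 and mt-Nd5 were at -0.46 ± 0.10, -0.26 ± 0.07, -0.32 ± 0.09 and -0.29 ± 0.09. Of the 10 genes, edgeR adjusted over the list alone called 6 lower and DESeq2 called 1. The share of counts in mitochondrial genes was 0.853 ± 0.0603% in Scr and 0.691 ± 0.0392% in Mir (SD, n = 3), with no overlap between groups (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). The 10 most abundant genes held 3.18 ± 0.127% of counts in Scr and 2.76 ± 0.0232% in Mir (exact permutation p = 0.1). Haemoglobin genes held 0.0548 ± 0.0295% and 0.0207 ± 0.0315% (exact permutation p = 0.3), and 16915 ± 343 and 16608 ± 66.9 genes had at least 10 counts (exact permutation p = 0.4). After thinning to the smallest library, 23224 ± 56.1 genes in Scr and 22314 ± 274 in Mir had at least 1 count (exact permutation p = 0.1).

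The remaining signalling and state lists did not pass camera at the preset settings, and some passed under the other settings given with them. Of 24 Notch genes 17 had higher means (median 0.10, camera adjusted p 0.124), with Nrarp at 0.38 ± 0.15 beside Dll1, Notch1 at 0.37 ± 0.16 and Dll4 at -1.30 ± 0.52. That p was 0.0165 without Mir replicate 1, 0.0472 without Scr replicate 1, 0.0378 without a filter and 0.00514 with the endothelial covariate. Of 17 FGF/ERK genes 12 had lower means (median -0.24, camera adjusted p 0.266), with Fgfr3 at 0.95 ± 0.21 and the feedback genes Dusp6, Spred2 and Il17rd at -1.27 ± 0.47, -0.57 ± 0.21 and -0.74 ± 0.36. The FGF/ERK list came past the threshold downward without Mir replicate 3 (camera adjusted p 0.00978) and without both Scr replicate 2 and Mir replicate 3 (0.0365), and pointed up without Mir replicate 1 (0.953) and with the endothelial covariate (0.173). Adherens junction and polarity genes were spread around 0 (20 of 35 higher, median 0.04, camera adjusted p 0.334), with Ctnna1 at 0.45 ± 0.09, Llgl1 at 0.27 ± 0.08, Pard6g at -0.45 ± 0.16 and the cadherin Cdh2 at 0.16 ± 0.10 (edgeR adjusted p 0.496). Of 31 matrix and integrin genes 15 had higher means, with a median of -0.02, a mean of -0.23 and camera pointing up (adjusted p 0.611), among them the proteoglycan genes Sdc3 (0.54 ± 0.10), Gpc1 (0.66 ± 0.13) and Vcan (-0.68 ± 0.15). Camera pointed down for this list without Scr replicate 3 (adjusted p 0.516) or Mir replicate 3 (0.849), and reached 8.63e-05 upward with the endothelial covariate. Adjusted over the list alone, edgeR called 1 Notch, 1 FGF/ERK and 2 adherens junction genes higher, and 2 matrix genes higher and 1 lower. DESeq2 called 1, 1 and 2 higher, and 3 matrix genes higher and 2 lower.

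The p53 and apoptosis list had 12 of 19 means lower (median -0.06, camera adjusted p 0.507), with Pmaip1 at -2.24 ± 0.74, Plk2 at -1.28 ± 0.56, Rrm2b at -0.48 ± 0.21 and Ckap2 at 0.29 ± 0.19. The machinery of microRNA processing and silencing had 8 of 13 means higher (median 0.05, camera adjusted p 0.688), with Tnrc6c at -0.32 ± 0.10, Tnrc6a at -0.26 ± 0.10, the exporter gene Xpo5 at 0.37 ± 0.12 and Tarbp2 at 0.25 ± 0.14. The integrated stress response had 11 of 17 means higher (median 0.04, camera adjusted p 0.827), with Vldlr at -0.62 ± 0.31, Ddit3 at -0.26 ± 0.16, Trib3 at 1.58 ± 1.06 and Ddit4 at 0.60 ± 0.42. It was called downward without Mir replicate 3 (camera adjusted p 0.0234) and without both Scr replicate 2 and Mir replicate 3 (0.0120), and upward without Mir replicate 1 (0.0458) and with the endothelial covariate (1.07e-05). Interferon response genes had 19 of 28 means higher (median 0.26, camera adjusted p 0.163), with Dhx58 at -0.82 ± 0.44, Ifit2 at -0.49 ± 0.35, Ifi27 at 0.60 ± 0.44 and Mx2 at 0.73 ± 0.55. Their median levels were 0.96, 0.69 and 0.48 in Scr replicate 3 and Mir replicates 2 and 3, and -0.61, -0.38 and -0.20 in the other libraries. The interferon list was called upward without Scr replicate 3 (camera adjusted p 4.43e-10) or Mir replicate 1 (0.000840) and without a filter (0.0493), and pointed down without Scr replicate 1 (0.702). For these 4 lists, 0 genes passed edgeR adjusted over the list alone, and 0 passed DESeq2; at an unadjusted p under 0.05 over all genes the edgeR count was 2450.

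Of the other cell types that the sorted population could hold besides progenitors and their neurons, 4 had marker lists that ranked lower in Mir in the camera test, with a wide spread between libraries. All 16 inhibitory neuron markers had lower means, with a median of -1.60 and a camera adjusted p of 4.70e-08 (adjusted p = 0.424 with an estimated correlation). Sst, Dlx6, Dlx5 and Gad2 were at -2.70 ± 0.82, -2.02 ± 0.71, -1.49 ± 0.51 and -1.48 ± 0.55. All 13 endothelial and pericyte markers had lower means, with a median of -2.65 and a camera adjusted p of 7.57e-07 (adjusted p = 0.424 with an estimated correlation), among them Kdr (-3.58 ± 1.38), Rgs5 (-3.12 ± 1.33), Esam (-2.47 ± 0.99) and Igfbp7 (-2.07 ± 0.82). All 12 microglia markers had lower means, with a median of -1.46 and a camera adjusted p of 1.49e-05 (adjusted p = 0.424 with an estimated correlation), among them P2ry12 (-3.78 ± 0.94), Ctss (-3.07 ± 1.35), Trem2 (-2.77 ± 1.27) and Aif1 (-1.62 ± 1.08). Of 7 erythroid markers 6 had lower means, with a median of -1.30 and a camera adjusted p of 0.00536 (adjusted p = 0.489 with an estimated correlation). The erythroid call was lost without Mir replicate 2 (camera adjusted p 0.103) and with the endothelial covariate (0.0638), and the globin genes Hbb-bt, Hba-x and Hbb-y were at -2.08 ± 1.24, -2.03 ± 1.32 and -1.47 ± 1.54, beside Alas2 at -1.02 ± 0.97. Adjusted over the list alone, edgeR called 0 members of these 4 lists, and DESeq2 called 2 inhibitory neuron markers lower and 0 others.

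Library by library, the summed level of the inhibitory neuron markers was 463, 1720 and 633 CPM in Scr replicates 1, 2 and 3 and 277, 250 and 593 CPM in Mir replicates 1, 2 and 3. For the endothelial markers these sums were 173, 406 and 46.7 CPM in Scr and 7.5, 32.0 and 85.1 CPM in Mir. For the microglia markers they were 42.5, 98.7 and 133 CPM in Scr and 30.8, 26.2 and 90.2 CPM in Mir. Erythroid markers summed to 249, 866 and 570 CPM in Scr and to 54.4, 1.60 and 580 CPM in Mir. Each of these 4 sums lay within the range of the Scr libraries in Mir replicate 3. Of the 48 members of these 4 lists, 44 lay below each Scr library in Mir replicate 1, 44 in Mir replicate 2 and 1 in Mir replicate 3.

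The 6 Cajal-Retzius markers had lower means (median -0.40, camera adjusted p 0.0761, 0.0137 without Mir replicate 3, and 0.0221 without both Scr replicate 2 and Mir replicate 3), with Reln at -1.30 ± 0.35, Calb2 at -1.14 ± 0.83, Cacna2d2 at -0.34 ± 0.56 and Ndnf at -0.46 ± 0.88. Of 4 oligodendrocyte precursor markers, 2 had higher and 2 lower means, with a median of 0.13, a mean of -0.09 and camera pointing up at an adjusted p of 0.811 (0.0385 without Scr replicate 2, and pointing down without Scr replicate 1 or 3). Olig2 was at 0.87 ± 0.45, Olig1 at 0.38 ± 0.86, Cspg4 at -1.49 ± 0.48 and Pdgfra at -0.12 ± 0.79. Of 6 meningeal fibroblast markers 4 had higher means (median 0.84, camera adjusted p 0.75), through Mir replicate 2, where Col3a1 was at 88.1 CPM and Col1a1 at 34.6 CPM against Scr means of 6.30 ± 1.97 and 5.47 ± 1.80 CPM (SD, n = 3). Without Mir replicate 2 that list was called downward (camera adjusted p 0.0306) and without Mir replicate 1 upward (0.00413), and Col1a2 and Ptgds were at 2.74 ± 1.55 and 0.50 ± 0.42. The choroid plexus list had 2 measured members, Kcnj13 at 0.93 ± 0.58 and Otx2 at -0.32 ± 0.89, too few to test. With edgeR adjusted over the list alone, and with DESeq2, the calls were 1 Cajal-Retzius marker lower and 0 members of the other 3 lists.

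Over the 28 lists tested, camera called 8 higher and 6 lower, while 0 were called with an estimated correlation (smallest adjusted p 0.424) and 0 with the directional form of fry (smallest adjusted p 0.209). The mixed form of fry, which gives no direction, had adjusted p-values of 0.000467 for Wnt activators, 0.00309 for Wnt inhibitors and 0.0635 for Wnt targets. Its adjusted p was 0.0020 for the microRNA machinery, 0.0829 for G1/S and 0.139 for G2/M. It was 0.00309 for Hippo/YAP targets and 0.0286 for cell cycle inhibitors and for FGF/ERK genes. Sonic hedgehog, matrix and mitochondrial genes each had 0.0308, and adherens junction genes 0.0336. The mixed form thus did not single out the Wnt lists. No member of any list passed edgeR over all genes.

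**Figure D2:**
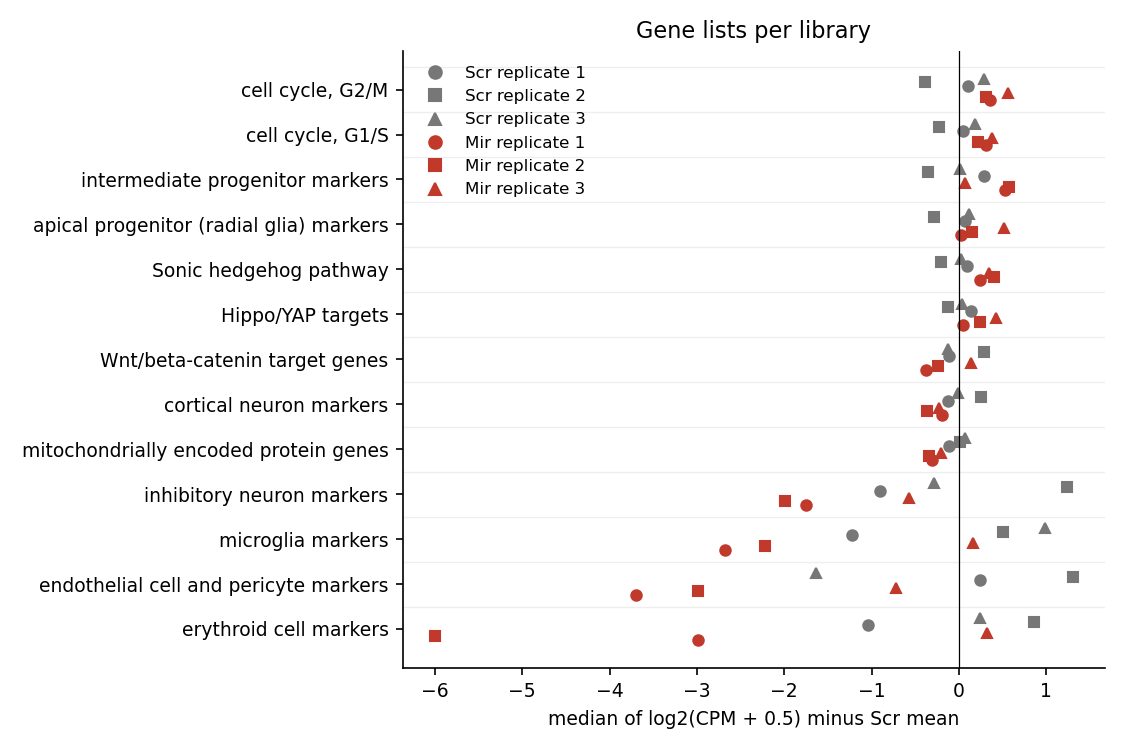
Median over the members of 13 gene lists of log2 (CPM + 0.5) minus the mean of the Scr libraries, for each library (Scr grey, Mir red). Endothelial markers lay at -3.70 and -2.98 in Mir replicates 1 and 2 and at -0.72 in Mir replicate 3, against 0.24, 1.31 and -1.64 in Scr replicates 1, 2 and 3, and G2/M genes at 0.36, 0.31 and 0.56, against 0.10, -0.39 and 0.29.

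A microRNA lowers transcripts that carry a match to its seed, and the planned comparison gave a small lower median that reversed once UTR length and expression were taken into account. Of 12693 genes with a searched 3′ UTR, 2190 carried a site for the seed CATGTGA and 10503 did not. The difference of their median log2 fold changes was -0.04, against an SD of 0.0077 over random gene sets, and it was 0.01 once trends with UTR length and mean expression were removed. Camera gave p = 0.131 downward (0.262 with an estimated correlation). The site TCACATG ranked 5781 of 16370 7-mers by the raw difference. The raw difference was -0.02 without Scr replicate 2 and -0.05 without Scr replicate 3. The 3′ UTR of Apc carries 1 such site, TCACATG within TGTGATCACATGGTGTG, at positions 563 to 569 of its 3971 nt, on chromosome 18 from 34319144 to 34319150 in exon 16 of 16. Fzd3 carries 2 sites, CACATGA, on the minus strand of chromosome 14 from 65200675 to 65200681 and from 65199076 to 65199082, in the last of its 7 exons, and Fzd8 carries 1, on chromosome 18 from 9217550 to 9217556. The 3′ UTRs of Ctnnb1, Axin2, Lef1, Ccnd1, Sfrp1 and Cdh2 carry 0, and the transcript used for Ank3 has no annotated 3′ UTR and was not searched.

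A scan over all 7-mers, made after this result had been seen, gave its lowest scores to other matches of the same hairpin strand. Genes with TTCATCA in the 3′ UTR had z = -8.50, those with CTTCATC -7.51, those with CATCACA -6.86 and those with TCATCAC -6.62, ranks 1, 2, 3 and 4 of 16370 by z. By the planned difference of medians these words ranked 46, 87, 209 and 137, and 30, 103, 78 and 35 with the trends with UTR length and expression removed, where TCACATG ranked 3253. In coding sequences the same 4 words had z = -7.17, -7.50, -6.21 and -5.83, ranks 2, 1, 5 and 6 of 16384, while ranks 3 and 4 went to TCATCAT (-6.49) and TCATCGT (-6.39), which are not complementary to the strand over all 7 bases. These words pair with bases 4 to 13 of the strand. The planned site TCACATG had z = -1.04 (rank 3899) in the 3′ UTR. Genes with 0, 1, 2 and 3 or more such sites in the 3′ UTR had median log2 fold changes of 0.02, -0.06, -0.11 and -0.21, with 9430, 2193, 727 and 343 genes, and medians of 0.04, 0.01, -0.03 and -0.07 once trends with length, expression and GC content were removed. The 3263 genes with any of them had z = -10.27, while those with a planned site had -0.04. Against the mean of the Scr libraries, z was -9.95, -8.92 and -7.88 in Mir replicates 1, 2 and 3, and single Scr libraries against the other Scr libraries gave -1.42 to 1.53. The words were picked on these same Mir and Scr libraries, and the Mir values share the same Scr mean. They are therefore no independent check. Apc carries 1 of these sites in its 3′ UTR, CATCACA on chromosome 18 from 34320056 to 34320062, and 7 in its coding sequence. Fzd3 carries 3 in the 3′ UTR, with an overlapping TCATCAC and CATCACA counted as 1 site, and Fzd8 and Elavl3 carry 2 each. Sfrp1, Axin2 and Racgap1 carry 0 in either part, and Ctnnb1 carries 2 in its coding sequence. Among the genes named as lower, Fbxo25 carries 1 in the 3′ UTR, while Edil3 and Ntrk3 carry 0 there and 1 each in the coding sequence. Ank3, also lower, carries 4 in its coding sequence. Of genes higher in Mir, Fzd8 carries the 2 given above and Prag1 carries 1 in its coding sequence. Named genes of both directions thus carry such sites. Ccnd1, near no change, carries 1 in the 3′ UTR.

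**Figure D3:**
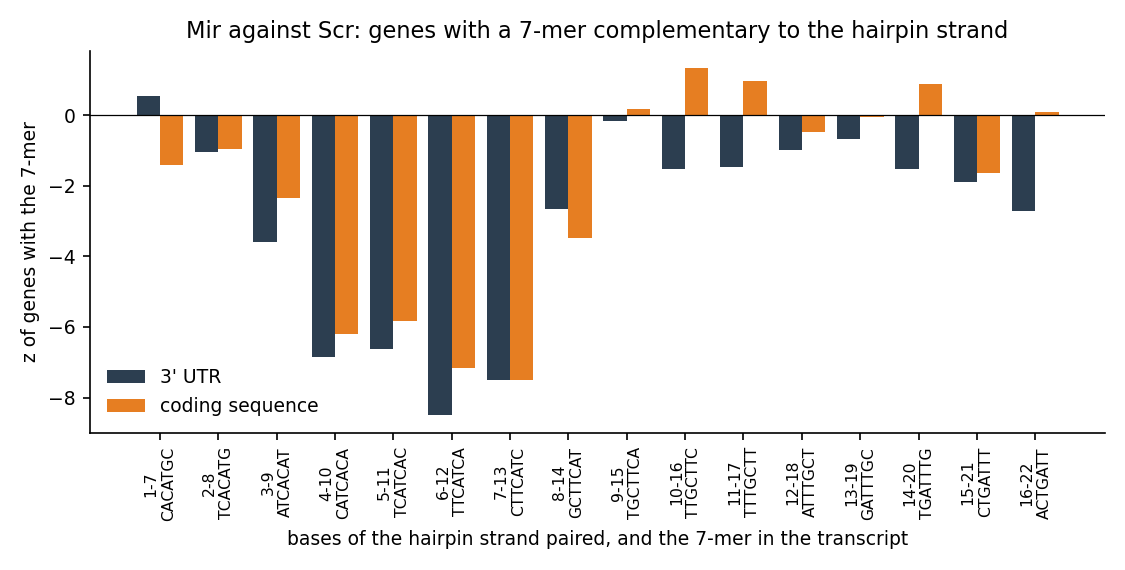
z of the genes that hold each 7-mer complementary to the 22 nt hairpin strand, from bases 1 to 7 on the left to bases 16 to 22 on the right, for 3′ UTRs (dark) and coding sequences (orange). The planned site TCACATG lies at -1.04 in 3′ UTRs, and TTCATCA, which pairs with bases 6 to 12, at -8.50.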

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

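The settings below were chosen in advance, except the tests without both Scr replicate 2 and Mir replicate 3, with the endothelial covariate, with the block and an estimated correlation together, and with DESeq2 on fewer libraries or with the block, which were chosen after the result was seen. Under the other scalings, the robust fit, the filter at 50 counts, the threshold of 0.1, the fold limit and the omission of mitochondrial, haemoglobin and ribosomal protein genes, edgeR again called 0 genes higher and 1 lower. Other settings moved these counts, and the cause was not tested. DESeq2 gave 247 higher and 333 lower, edgeR without a filter 15 and 16, limma-voom 0 and 0, the endothelial covariate 0 and 0, and both libraries left out 10 and 19. Leaving out single libraries gave 0 higher and 0 to 2 lower in edgeR, with the 0 without Mir replicate 1 or 2 and the 2 without Mir replicate 3. In DESeq2 it gave 46 (without Mir replicate 2) to 318 (without Mir replicate 3) higher and 72 to 821 lower, without the same libraries. Depth limits markers such as P2ry12, Trem2 and Aif1, which lay below 1 CPM in Mir replicates 1 and 2.

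The labels do not say whether equal replicate numbers mark paired libraries. The correlations of the deviations of equally numbered libraries were 0.224, -0.148 and -0.103, which neither shows nor excludes a pairing. With the replicate number as a block, edgeR called 0 genes higher and 0 lower (Ftl2-ps at -7.25, adjusted p 0.0524), DESeq2 196 and 252, and camera 8 lists higher and 6 lower. The block ended the call of the cell cycle inhibitors (camera adjusted p 0.0832), added that of the interferon response (0.0422) and turned the meningeal fibroblast list downward (0.912). With the block and an estimated correlation, camera called 0 lists higher and 0 lower. Adjusted p-values were then 0.608 for radial glia, 0.606 for intermediate progenitors, 0.56 for cortical neurons, G1/S and G2/M, and 0.985 (downward) for meningeal fibroblasts.

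For gene lists, camera on ranks, DESeq2-type size factors, library totals and the filters gave 7 to 10 higher and 6 lower. The filter at 50 counts ended the call of the cell cycle inhibitors (0.0662), and no filter added Notch genes (0.0378) and the interferon response (0.0493). With an estimated correlation 0 were higher and 0 lower, and likewise with fry. The camera adjusted p with an estimated correlation was 0.511 for radial glia and 0.424 for intermediate progenitors, cortical neurons, G1/S and G2/M. By fry the adjusted p was 0.424 for radial glia, 0.347 for intermediate progenitors, 0.24 for cortical neurons, 0.292 for G1/S and 0.302 for G2/M. Both libraries left out gave 5 lists higher and 9 lower, with camera adjusted p-values of 0.721 for radial glia and 0.012 for the integrated stress response, both downward. The endothelial covariate gave 0.133 for intermediate progenitors and, turned upward, 0.173 for Wnt targets and for FGF/ERK genes. Directions also turned without a filter for the p53 list (0.901, upward) and with the filter at 50 counts for the integrated stress response (0.906, downward). The cause was not tested for any of these.

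Leaving out single libraries gave 7 to 12 lists higher, the 12 without Mir replicate 1, and 6 to 10 lower, the 10 without Mir replicate 3. Camera adjusted p-values ranged from 3.57e-10 to 0.286 for radial glia, 0.0137 to 0.953 for Wnt targets, 0.169 to 0.874 for Wnt activators, 0.00978 to 0.953 for FGF/ERK genes and 0.169 to 0.849 for matrix genes. They ranged from 4.43e-10 to 0.702 for the interferon response, 0.0234 to 0.992 for the integrated stress response, 0.0385 to 0.975 for oligodendrocyte precursors and 0.00413 to 0.747 for meningeal fibroblasts. Of these, the radial glia list and Wnt targets kept their direction and the others turned in at least 1 of the 6 fits.

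The difference of medians of genes with a planned seed site was -0.0484 for the 8mer, -0.0482 for 7mer-m8 or 8mer sites, -0.0554 for the other strand of the hairpin, -0.0228 with both libraries left out and 0.011 with the trend removed. It ranged from -0.0542 (without Scr replicate 3) to -0.0241 (without Scr replicate 2). Of genes near no change, both libraries left out gave log2 fold changes of -0.0049 for Hes5, 0.12 for Axin2, -0.019 for Sox2 and -0.41 for Hes1. Leaving out single libraries gave -0.37 to 0.031 for Axin2, -0.086 to 0.23 for Sox2, -0.26 to 0.46 for Hes1, -0.053 to 0.20 for Tbr1 and -0.28 to 0.11 for Ccnd1. Over all list tests and settings, 381 kept direction and side of the threshold, 54 lost the call, 21 gained it and 19 turned. For fold changes of named genes these numbers were 264, 3, 24 and 13.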

Other observations

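Each test in this part was chosen after the result it bears on was seen, except that of the second marker list and that of the endothelial covariate, whose bounds were written before their own values were seen but after the pattern per library was known. Both replaced tests on Mir replicate 3 alone, in which z for the matches to bases 4 to 13 was -7.88 and 1 of 48 marker genes lay below each Scr library, with the same outcome.

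The pools differed in sex-linked transcripts within both groups; these genes were looked at outside the naming rule, after values had been seen. Xist, the transcript of the inactive X chromosome, was at 342, 0.652 and 253 CPM in Scr replicates 1, 2 and 3 and at 239, 1.72 and 373 CPM in Mir replicates 1, 2 and 3. The Y-linked gene Eif2s3y was at 76.9, 151 and 73.4 CPM in Scr and at 93.4, 172 and 0.0679 CPM in Mir, and Kdm5d, Uty and Ddx3y were at 0 in Mir replicate 3. Tsix, which overlaps Xist on the other strand, followed it at 283, 0.217, 219, 224, 2.11 and 314 CPM in the same order of libraries, and its counts cannot be separated from those of Xist without strand. Among processed pseudogenes, Gm45456 was below 0.25 CPM in Scr replicates 1 and 2 and at 17.7 CPM in Scr replicate 3, and Gm4742 was at 0.0724 CPM in Scr replicate 2 and at 13.1 and 9.21 CPM in Scr replicates 1 and 3.

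With 3 against 3 libraries there are 10 splits, so the share of splits as large cannot go below 0.1. For edgeR the real split gave 1 gene and the highest other 2 (2 of 10 as large), and for gene lists 14 and 15 (5 of 10). DESeq2 gave 580 genes for the real split and 680 for the highest other (2 of 10), the split of Scr replicate 1 with Mir replicates 1 and 2 against the other libraries. That split calls many genes and points to a structure of the samples other than the group. For the planned seed sites the difference of medians was -0.03704 and the highest other -0.03414 (1 of 10), and for the matches to bases 4 to 13 z was -10.27 and the highest other -7.481 (1 of 10). These matches were picked on the real split, so its first place was favoured by that choice and does not test chance. In the false splits z lay from -7.481 to -3.243 or from 4.095 to 5.504.

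The lower levels of genes that match bases 4 to 13 of the hairpin strand were seen in each Mir library. These libraries also served to pick the matches, so they do not replicate the result. In genes without such a site in the 3′ UTR, a site in the coding sequence went with z = -7.851, as a strand that starts downstream of the annotated end, and so uses other bases as its seed, would give; yet in that test TCATCGT, which is not complementary to the strand over all 7 bases, had z = -6.071, within the range of the 4 words (-6.593 to -5.218), which stays unexplained. Base composition as the whole cause is argued against by the means of the 696 7-mers of the same composition. In 3′ UTRs their mean z was -0.5981 with an SD of 1.06 and a lowest of -5.233. That lowest had to lie above the 4 words, which were picked as the lowest of the same scan. Their distance from that mean is for the same reason no test. In that coding test the mean was -0.7491, the SD 1.13 and the lowest -5.014, close to the highest of the 4 words, -5.218. CAACGCC, of another composition and also not complementary to the strand, had z = -5.147 there. Endothelial content as the whole cause is also argued against, since z was -9.7 with the endothelial covariate. That covariate cannot speak for each other cell type: microglia markers were highest in Scr replicate 3, where endothelial markers were lowest of the Scr libraries. A hypothesis, found and tested on the same data, is that the hairpin may act here mainly through a shifted seed rather than through bases 2 to 8. The ends of the small RNA made in these cells and the seed of the scrambled hairpin were not tested and stay open.

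The lower inhibitory neuron, endothelial, microglial and erythroid markers may come from fewer sorted cells of these types in Mir replicates 1 and 2, which the GFP gate should largely have removed. Scr replicate 2 also had the highest inhibitory neuron, endothelial and erythroid sums (1720, 406 and 866 CPM), but not the highest microglia sum (98.7 CPM). More such cells in that library may add to the difference, and these contributions were not separated. In a second list of 52 markers of the same types, 31 of 35 measured members were in Mir replicate 3 at or above the lowest Scr library, while 31 lay below each Scr library in Mir replicate 1 and 27 in Mir replicate 2. A library no different from the Scr libraries would also have most members at or above the lowest of them. The count for Mir replicate 3 alone is therefore weak evidence. An effect of miR-3607 that puts each Mir library below each Scr library is argued against, since 1 of 48 members lay there in all 3. A smaller effect cannot be excluded, because the Scr libraries spread widely, from 46.7 to 406 CPM for the endothelial sum. In Mir replicate 3 the list medians against the Scr mean were -0.57 (inhibitory neurons), -0.72 (endothelial), 0.17 (microglia) and 0.33 (erythroid). Among the most abundant members were Hbb-bt, at 132 ± 66.0 CPM in Scr and 31.3 ± 46.8 CPM in Mir (SD, n = 3), and Gad2, at 78.8 ± 57.0 CPM in Scr (SD, n = 3) and 22.1, 16.8 and 45.9 CPM in Mir replicates 1, 2 and 3, with Scr replicate 1 below Mir replicate 3. Differences in dissection, gating or sex of the pools were not tested.

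Ftl2-ps, at 1 count in each Mir library, was the sole gene below 0.25 CPM throughout a group and at 5 CPM or more in each library of the other. Repression through the sequence it shares with Ftl1 is argued against, since the log2 fold change of Ftl1 was -0.15223 ± 0.19. A variant that differs between pools of embryos, whose strain the labels give in 2 ways, cannot be told apart from an effect of the hairpin. Of 46 autosomal genes that went between these levels within a group, 2 were processed pseudogenes, no more than their share (one-sided Fisher's exact p = 0.776), and these are too few to decide. The pseudogene carries 0 matches to bases 4 to 13 of the strand.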
